A study of Mus musculus with 7 samples.

How the data were processed

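RNA was measured in lung endothelial cells of mouse embryos collected at E18.5, from 3 samples labelled wild-type and 4 labelled as lacking Sash1 in both gene copies. Per the labels, wild-type and knockout embryos were littermates on a C57BL/6 background and were genotyped by PCR, and viable cells carrying CD31 and lacking CD45 and CD326 were sorted from dissociated lungs and frozen. CD31 marks endothelial cells, CD45 marks leukocytes and CD326 marks epithelial cells. RNA with an integrity number above 7 was amplified and labelled by a whole-transcriptome method for small inputs and hybridised to 1-colour Affymetrix arrays, 1 per sample. Nothing in the labels states that each sample was a separate embryo or litter, so p-values measure the spread between these samples, which may in part be technical.

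The authors deposited 1 processed value per probe set and array. Per the submitters' processing notes, these were made with RMA (background correction, quantile normalization and probe set summary) in Affymetrix Expression Console 1.1. That the deposited values are on the log2 scale was read from the values themselves, which have 2 decimals. Array medians over the 41345 probe sets were 3.93, 4.01 and 4.03 for the arrays labelled wild-type 1 to 3, and 4.00, 3.86, 3.92 and 3.95 for those labelled knockout 1 to 4. No reads stand behind array values, so sequencing depth does not apply, and the number of arrays limits the precision.

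Probe sets were named through the platform annotation held by GEO, updated through a mouse RefSeq gene table of assembly GRCm38.p6, in which 99.2% of the gene identifiers were found. Of the probe sets, 23521 had 1 gene symbol (22180 distinct genes), 1814 had several and 16010 had none listed. A gene with several probe sets was represented by the brightest over all 7 arrays, and the dimmest 25% of genes by that mean (5543 genes, below a log2 value of 2.98) were left out, which left 16637 genes. The genome build behind the array annotation was not given in the sources used here, so the RefSeq table served only for names, chromosomes and neighbouring genes, and no coordinates are printed.

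Knockout-labelled and wild-type-labelled arrays were compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with genotype as the only term. Differences are knockout-labelled minus wild-type-labelled means on the log2 scale, tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All 28 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, with an estimated correlation and with fry beside it. The lists covered nitric oxide and cGMP signalling, general capillary, aerocyte, arterial, venous, lymphatic and pan-endothelial markers, VEGF and tip cell genes, BMP and TGF-beta signalling, shear stress and KLF2, NF-kB activation, interferon response, cell cycle, glycolysis and hypoxia, basement membrane, glucocorticoid response, angiocrine factors, junctions and actin adhesion, p53 targets, immediate early and dissociation stress genes, lung epithelium, fibroblast and mural cells, leukocytes, erythroid cells, platelets, mesothelium, cytosolic ribosomal proteins and oxidative phosphorylation. Mean values of each list were also compared with an exact permutation test over the 35 ways to split 7 arrays into 3 and 4, for which the smallest possible p is 0.0286. A list of sex-linked genes served only to read the sex of the embryos. Principal components were computed over the tested genes without Sash1. Genes near Sash1 were tested for enrichment within 20 Mb with Fisher's exact test, using genes with an unadjusted p under 0.01 because fewer than 10 were called.

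The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have come later. Named genes were Sash1 and its relatives Sash3 and Samsn1, the 12 genes with the largest differences in each direction among called genes without overlap between labels, the 4 members of each list with the smallest unadjusted p, and Nos3, Thbs1, Sftpa1, Sftpb, Sftpc, Pecam1, Ptprc and Epcam. Unnamed gene models, olfactory and vomeronasal receptors and small RNA genes took no place. Places left over in a direction went to the genes of smallest unadjusted p with a log2 difference of at least 0.5 in size, described as not passing.

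The alternatives were no filter on dim genes or a filter on 50% of them, quantile normalization or median centring of the deposited values, an intensity trend with robust moderation, array weights, the mean of a gene's probe sets or every probe set on its own, the replicate number as a fixed or random block, sex as a covariate, X and Y genes left out, no variance moderation, a threshold of 0.1, windows of 10 Mb or the whole chromosome, and each array left out in turn. A fit without the arrays labelled wild-type 3 and knockout 3 was added after seeing the data. The tests were checked on simulated data with the spread of these genes and 200 changed genes among 16637. In that simulation 10.7% of genes changed by a log2 of 0.5 were recovered, 74.4% of those changed by 1 and 97.7% of those changed by 2, with 6.45 false calls per draw. The simulated genes were independent throughout, and 0.08 lists were called per draw without an effect. In these data the estimated correlation between members was 0.73 for cell cycle genes and 0.21 for BMP and TGF-beta genes. The simulated rate therefore does not carry over to them. Figures were drawn with matplotlib 3.10.9.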

Results

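Expression was profiled in endothelial cells sorted from the lungs of mouse embryos at E18.5, shortly before birth, in 3 samples labelled wild-type and 4 labelled Sash1-knockout. The series asks how loss of Sash1 in lung endothelium relates to surfactant and nitric oxide signalling. Pecam1, which encodes the sorting antigen CD31, had a log2 signal of 11.12 ± 0.03 (SD, n = 3) on the arrays labelled wild-type and 11.12 ± 0.07 (SD, n = 4) on those labelled knockout. Ptprc, which encodes CD45, measured 4.67 ± 0.20 and 4.34 ± 0.56, and Epcam, which encodes CD326, measured 5.03 ± 0.34 and 4.88 ± 0.55. The number of arrays limited the precision, with a median 95% confidence interval of 0.345 log2 units to either side of a gene's difference.

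Sash1, which encodes a scaffold protein with SAM and SH3 domains, was represented by probe set 17239113. Its log2 signal was 9.02, 8.73 and 8.33 on the arrays labelled wild-type 1, 2 and 3, and 8.29, 8.21, 8.68 and 8.13 on those labelled knockout 1, 2, 3 and 4. Its mean difference was -0.37 (SE 0.20, 95% confidence interval -0.83 to 0.10), or 77.6% of the wild-type-labelled level (95% confidence interval 56.3% to 107%), with an adjusted p of 0.971 in limma. Single arrays moved this difference, to -0.20 without the array labelled wild-type 1 and -0.55 without the array labelled wild-type 3. Sash3 and Samsn1, its relatives, differed by -0.05 and -0.11, signs that turned without the array labelled wild-type 2, and that of Sash3 also with quantile normalization. Sash1 thus went against the label of the array labelled wild-type 3, which lay near the knockout-labelled values, and of the array labelled knockout 3, which lay near the array labelled wild-type 2. The labels do not say which part of Sash1 was removed, and a probe set outside that part checks nothing. For this reason groups are named by their labels throughout, and every direction given rests on those labels.

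The arrays did not separate by label across the other genes. The first principal component, computed without Sash1, carried 36.5% of the variance and placed the arrays labelled wild-type 1, wild-type 2 and knockout 3 at 29.6, 18.1 and 21.0. The arrays labelled wild-type 3 and knockout 1, 2 and 4 lay at -23.2, -10.2, -20.3 and -15.0, and the labels did not differ on this component (exact permutation p = 0.429). Correlations over all 41345 probe sets, Sash1 included, averaged 0.9713 between arrays of the same label and 0.9709 between arrays of different labels. They were highest, at 0.9802, between the arrays labelled wild-type 1 and knockout 3.

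**Figure D1:**
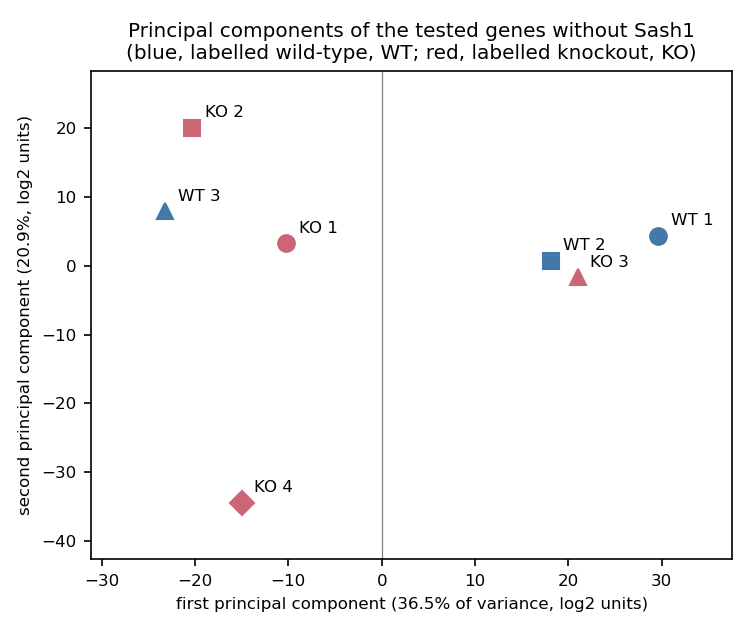
First and second principal components (log2 units) of the 16637 tested genes without Sash1, with 1 point per array, blue for arrays labelled wild-type and red for arrays labelled knockout. The arrays labelled wild-type 1, wild-type 2 and knockout 3 lie at positive values of the first component, from 18.1 to 29.6, and the other arrays at negative values.

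Single genes were compared between labels to find those altered by loss of Sash1. Alg8, a glucosyltransferase of protein N-glycosylation, was higher by 0.53 (95% confidence interval 0.29 to 0.77) on the arrays labelled knockout, Pparg, a nuclear receptor of lipid metabolism, by 0.55 (0.23 to 0.86), Wif1, a secreted Wnt inhibitor, by 0.60 (0.30 to 0.90), and Akap5, an anchoring protein for kinases, by 0.94 (0.38 to 1.5). Csrp3, a muscle LIM protein, differed by -0.64 (-0.90 to -0.38), Chd7, a chromatin remodeller, by -0.54 (-0.88 to -0.19), Bcl2l1, which encodes the survival protein BCL-XL, by -0.57 (-1.0 to -0.14), and Myl7, the atrial myosin light chain, by -1.26 (-2.27 to -0.26). None of these differences passed the test, since all had an adjusted p of 0.971.

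The other genes of smallest unadjusted p with higher values on the arrays labelled knockout were Krtap5-3, Ceacam11, Ap3s2, Aatf, Smim26, Ska3, Zmat5 and Fbxo21, and all 12 in this direction differed by 0.52 to 0.94 without overlap between labels. Krtap9-5, H2al1o, Lrrtm2, Gcnt7, Gal3st2b, Slc16a11, Arih2 and Dusp16 completed the 12 with lower values, of which 5 had no overlap. The Csrp3 value on the array labelled knockout 4 (3.93), the Fbxo21 value on the array labelled knockout 3 (6.30), and the Slc16a11 and Krtap9-5 values on the array labelled knockout 2 (3.78 and 3.01) stood apart from the other knockout-labelled arrays. Csrp3, Slc16a11 and Krtap9-5 lay at 4.54 or lower on the arrays labelled knockout, below the array medians of the tested genes (5.30 to 5.41). Of 16637 genes tested with limma, 0 passed an adjusted p of 0.05 and 0 passed 0.1. At an unadjusted p under 0.05 there were 556 genes, 396 higher and 160 lower on the arrays labelled knockout, where chance would give 832. Without variance moderation 0 genes passed and 417 had an unadjusted p under 0.05. In 408 genes, or 2.45%, the labels did not overlap, against a chance share of 5.71%. The unadjusted count was 295 without the array labelled wild-type 2, 1314 without the array labelled wild-type 3 and 1779 without the arrays labelled wild-type 3 and knockout 3, a fit chosen after seeing the data, and 0 genes passed in each.

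Single arrays carried much of what follows. Leaving out 1 array moved the difference by over 1.5 times, either way, or turned its sign for 95 of 139 named genes (16 turned), and did so for the mean difference of all 24 lists that did not pass and all 4 that did.

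Nitric oxide signalling and surfactant genes bear on the stated question. Nos3, the endothelial nitric oxide synthase, differed by 0.06 (95% confidence interval -0.27 to 0.40), with log2 values of 6.85 ± 0.21 (SD, n = 3) on the arrays labelled wild-type and 6.92 ± 0.19 (SD, n = 4) on those labelled knockout, and its sign turned without the array labelled wild-type 3 (-0.02) or knockout 3 (-0.03). Thbs1, thrombospondin 1, a secreted inhibitor of nitric oxide signalling, differed by -1.02 (-2.90 to 0.85). Its values were 8.14, 8.49 and 5.83 on the arrays labelled wild-type and 6.66, 5.46, 7.92 and 5.82 on those labelled knockout. Gucy1b1, a subunit of the nitric oxide receptor guanylate cyclase, was at 7.11, 7.04 and 7.17 on the arrays labelled wild-type and between 7.28 and 7.66 on those labelled knockout, a difference of 0.30 (0.03 to 0.56). The arginine transporter Slc7a1 differed by -0.70 (-1.64 to 0.24), Gch1, which starts the synthesis of the synthase's cofactor, by -0.41 (-1.14 to 0.32), and Hsp90aa1 by -0.18 (-0.50 to 0.13). Gch1 differed by -0.08, Slc7a1 by -0.43 and Hsp90aa1 by -0.09 without the array labelled wild-type 1, and without wild-type 3 these were -0.65, -1.14 and -0.33. Thbs1 differed by -0.52 without wild-type 2 and -1.85 without wild-type 3. None of these genes passed the test (adjusted p of 0.971 to 0.982). Of the 29 tested members of the nitric oxide list, 17 had positive and 12 negative differences, and 0 passed over all genes or adjusted over the list alone. The list's median was 0.02 while its mean was -0.03 and the direction of its test was down, at an adjusted p of 0.845, but up without the array labelled wild-type 1 or knockout 4.

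Surfactant transcripts come from alveolar epithelial cells, which the sort was set to exclude. Epithelial transcripts were measured on all arrays all the same. The lung epithelium list averaged 8.38, 7.98 and 7.32 on the arrays labelled wild-type and 8.10, 7.55, 8.22 and 6.47 on those labelled knockout. Array medians of the tested genes were 5.30 to 5.41. Sftpc measured 11.97, 11.90 and 11.92 on the arrays labelled wild-type and 12, 11.86, 11.97 and 10.20 on those labelled knockout, a difference of -0.42 (95% confidence interval -1.45 to 0.61). Sftpb differed by -0.72 (-2.78 to 1.35) and Sftpa1 by -1.0 (-3.37 to 1.37), with the array labelled knockout 4 lowest for each, at 6.13 and 4.70. Without that array Sftpc differed by 0.01, Sftpb by 0.10 and Sftpa1 by -0.05, and the mean difference of the lung epithelium list turned from -0.31 to 0.06. The list mean was -0.06 (adjusted p = 0.873), Sftpb -0.36 and Sftpa1 -0.58 without the array labelled wild-type 1, and Sftpb was -1.10 without knockout 3. This list passed without the array labelled wild-type 3 (-0.59, adjusted p = 0.0031), knockout 1 (-0.48, 0.0163) or knockout 3 (-0.52, 0.00594). It also passed with all arrays kept, under quantile normalization and with the replicate number as a random effect. In the lung epithelium list, 16 of 19 members had negative differences, with a median of -0.27 and an adjusted p of 0.0871, and 0 passed adjusted over the list alone. Within it the club cell gene Scgb1a1 differed by -0.41 and the junction gene Cldn18 by 0.23, a sign that turned without the array labelled wild-type 3. Scgb1a1 differed by -0.19 without knockout 4, -0.10 without wild-type 1, -0.24 without wild-type 2 and -0.90 without wild-type 3.

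**Figure D2:**
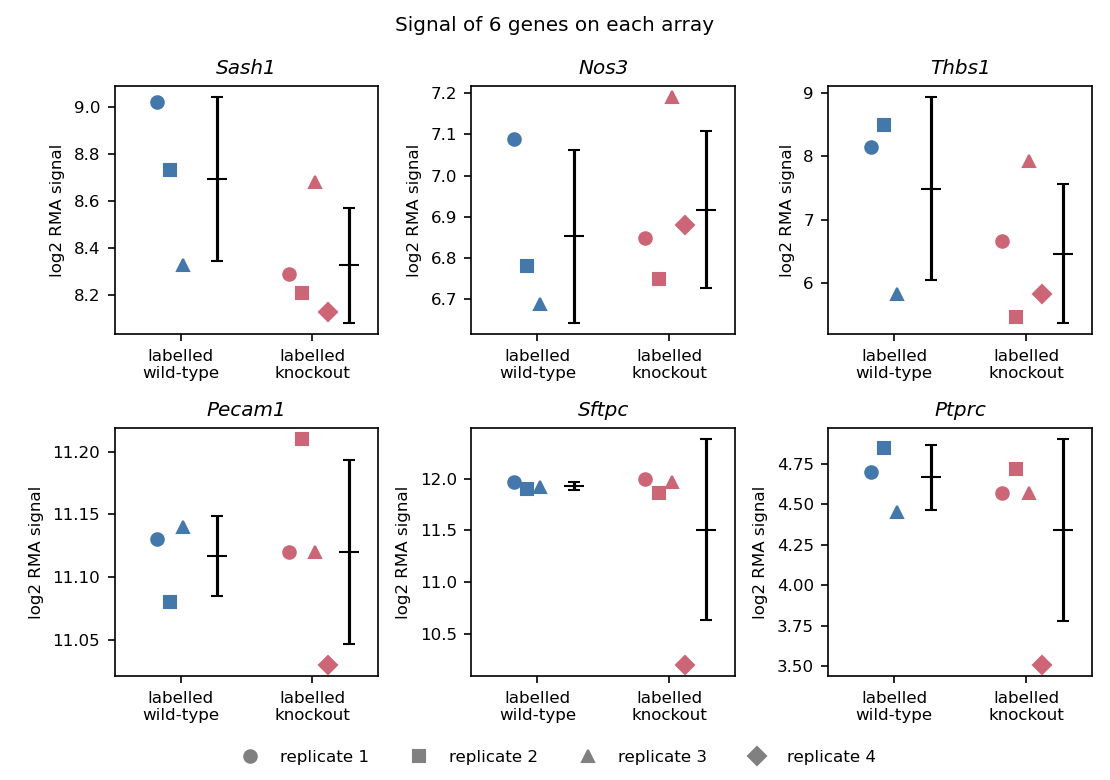
Log2 RMA signal of Sash1, Nos3, Thbs1, Pecam1, Sftpc and Ptprc on each array, blue for labelled wild-type and red for labelled knockout, with the marker shape giving the replicate number and bars giving the mean and SD of each label. Sash1 lies at 8.33 on the array labelled wild-type 3 and 8.68 on the array labelled knockout 3, and the array labelled knockout 4 is lowest for Sftpc (10.20) and Ptprc (3.51).

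Gene lists were compared to find shifts shared by related genes. Leukocyte markers had lower values on the arrays labelled knockout in 17 of 19 members, with a median difference of -0.22 and camera's adjusted p at 0.0047. The lysozyme gene Lyz1 differed by -1.82, the macrophage gene Cd68 by -0.52, Cd14 by -0.62 and the complement gene C1qb by -0.31. Without the array labelled knockout 4 Lyz1 differed by -0.33 and Cd68 by -0.25, and without the array labelled wild-type 1 Cd14 differed by -0.08. Without the array labelled knockout 2 Cd14 differed by -0.41 and C1qb by -0.13, without knockout 3 these were -0.95 and -0.51, and without wild-type 3 Cd14 differed by -1.14. Cell cycle genes had higher values in 26 of 29 members, with a median of 0.21 (adjusted p = 0.0154), among them the replication genes Mcm2 (0.46), Mcm4 (0.41) and Gins1 (0.24) and the mitotic kinase gene Plk1 (0.48). Glucocorticoid response genes had lower values in 14 of 17 members, with a median of -0.26 (adjusted p = 0.0154), among them Fkbp5 (-0.65), Sgk1 (-0.96), the metallothionein gene Mt1 (-1.01) and Zbtb16 (-0.26). BMP and TGF-beta genes had lower values in 17 of 24 members, with a median of -0.10 (adjusted p = 0.0318). The inhibitory members Smad7 (-0.41), Smad6 (-0.72) and Bambi (-0.21) stood beside the ligand gene Bmp2 (-0.59). Plk1 fell to 0.24, Mcm4 to 0.26, Fkbp5 to -0.43 and Bmp2 to -0.28 without the array labelled wild-type 1, and Gins1 to 0.14 without knockout 2. Without knockout 4 Mt1 was -0.60, Zbtb16 -0.16 and Bmp2 -0.37, and without wild-type 2 Mt1 was -0.64, Zbtb16 -0.17, Sgk1 -0.59, Smad6 -0.45 and Bambi -0.06. Without wild-type 3 the values were further from 0, at -1.62 for Mt1, -1.61 for Sgk1, -1.02 for Fkbp5, -0.40 for Zbtb16, -1.21 for Smad6 and -0.33 for Bambi. With an estimated correlation the adjusted p was 0.846 for each of these 4 lists, fry called 0 lists with a smallest adjusted p of 0.873, and 0 members passed over all genes or adjusted over the list alone.

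The glucocorticoid list averaged 8.18, 8.24 and 7.07 on the arrays labelled wild-type and 7.44, 7.2, 8.01 and 7.03 on those labelled knockout. BMP and TGF-beta genes averaged 7.82, 7.81 and 7.21 against 7.4, 7.32, 7.74 and 7.2. The immediate early and dissociation stress genes moved with them, at 8.43, 8.27 and 7.15 against 8.0, 7.14, 8.64 and 6.79. Leukocyte markers averaged 6.45, 6.21 and 5.76 against 6.08, 5.75, 6.19 and 5.19, and cell cycle genes 5.79, 6.29 and 6.27 against 6.09, 6.53, 5.95 and 6.69. In exact permutation tests of the list means the smallest p over all 28 lists was 0.229 (0.80 adjusted), and 22 of the 35 possible splits gave at least as many camera calls as the labels. Without the array labelled wild-type 1 the leukocyte, glucocorticoid and BMP lists had an adjusted p of 0.275 and cell cycle 0.914, and without the array labelled knockout 4 these were 0.159 and 0.668. Of the 4 lists, the leukocyte list alone passed without the array labelled knockout 2 (adjusted p = 0.0481), the glucocorticoid and BMP lists did not without the array labelled wild-type 2 (0.310 and 0.359), and BMP did not without the array labelled knockout 1 (0.0587) or with median centring (0.0518). The mean list differences rested on single arrays too. Cell cycle, at 0.20, fell to 0.03 without the array labelled wild-type 1, 0.07 without knockout 4 and 0.12 without knockout 2, and was 0.32 without knockout 3. The glucocorticoid list, at -0.41, was -0.23 without wild-type 1, -0.20 without wild-type 2 and -0.79 without wild-type 3. Leukocyte markers, at -0.34, were -0.18 without wild-type 1, -0.13 without knockout 4 and -0.53 without wild-type 3. BMP and TGF-beta genes, at -0.20, were -0.10 without wild-type 1 or wild-type 2, -0.13 without knockout 4, -0.40 without wild-type 3 and -0.31 without knockout 3.

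**Figure D3:**
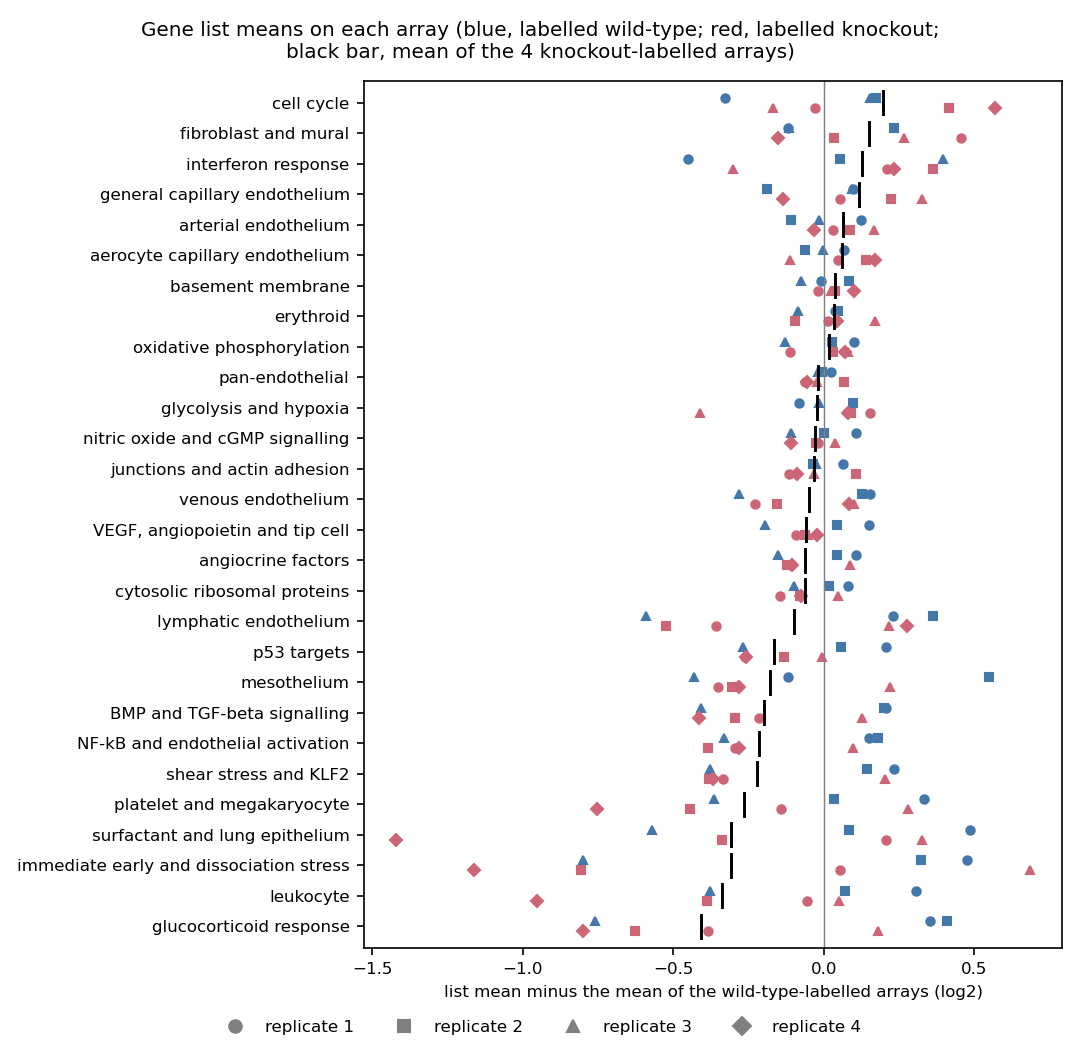
Mean log2 signal of each gene list on each array minus the mean of the 3 arrays labelled wild-type, blue for labelled wild-type and red for labelled knockout, with the marker shape giving the replicate number and a black bar at the mean of the 4 arrays labelled knockout. The bar is highest for cell cycle, at a difference of 0.20, and lowest for the glucocorticoid response, at -0.41, and arrays of both labels overlap for these lists. Without the array labelled wild-type 1 these differences were 0.03 and -0.23.

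No list of endothelial identity genes passed the test in the main comparison. The pan-endothelial list had a median of -0.04 (adjusted p = 0.464), with Calcrl at 0.34, Erg at 0.19, Flt1 at -0.15 and Egfl7 at -0.14. General capillary genes had a median of 0.08 (adjusted p = 0.445), with the chemokine gene Cxcl12 at 0.32, Hpgd at 0.70, Sema3c at 0.23 and Cd93 at -0.12. Aerocyte genes, of the capillary cells that line the gas exchange surface, had a median of 0.05 (adjusted p = 0.452), with Emp2 at 0.27, Igfbp7 at 0.26, the carbonic anhydrase gene Car4 at 0.22 and Tbx3 at -0.27. Arterial genes had a median of 0.01 (0.842), with Cxcr4 at 0.79, Jag1 at -0.33, Jag2 at -0.24 and Notch4 at 0.18. Venous genes had a median of -0.05 (0.549), with Vwf at -0.13, Amigo2 at -0.25, Nr2f2 at 0.17 and Slc6a2 at 0.09. Lymphatic genes had a median of -0.07 (0.266), with Prox1 at -0.12, Pard6g at -0.22 and Sned1 at -0.06. VEGF, angiopoietin and tip cell genes had a median of -0.06 (0.266), with the co-receptor gene Nrp1 at 0.41 and Mcam at -0.24. Of these 7 lists 0 passed in the main comparison, with 0 members adjusted over the list alone. With all arrays kept, the lymphatic list passed with array weights. Without the array labelled wild-type 3 the lymphatic list passed, with a mean difference of -0.39 (adjusted p = 0.0031) against -0.10 with all arrays, as did the VEGF list, at -0.15 (0.0499) against -0.06. The lymphatic mean was 0.08 without wild-type 2 and -0.22 without knockout 4, where Pard6g differed by -0.40. The test direction also turned for venous genes without wild-type 1, for arterial genes without wild-type 2, wild-type 3 or knockout 3, and for general capillary genes without knockout 3, and the sign of Nr2f2 turned without wild-type 3. Without wild-type 2 Hpgd differed by 0.27, Cxcr4 by 0.43, Cxcl12 by 0.20, Erg by 0.10, Notch4 by 0.07 and Sema3c by 0.00, and without wild-type 1 Jag1 differed by -0.17, Amigo2 by -0.08 and Calcrl by 0.20 (0.58 without wild-type 3).

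Signalling and structural lists also did not pass by limma's camera in the main comparison. Shear stress and KLF2 genes had a median of -0.06 (adjusted p = 0.0871), with Klf4 at -0.64 (95% confidence interval -2.22 to 0.94), Ptgs2 at -1.33 (-3.16 to 0.50) and Edn1 at -0.23, and the list mean was 8.09 on the array labelled knockout 3 against 7.50 to 7.55 on the other arrays labelled knockout. NF-kB and endothelial activation genes had a median of -0.18 (0.0674), with the chemokine gene Ccl2 at -1.06, Tlr4 at -0.41 and Csf1 at 0.31. Immediate early and dissociation stress genes had a median of -0.27 (0.0871), with Klf6 at -0.67, Myc at -0.57, Ier3 at 0.44 and Hsph1 at 0.22. Angiocrine factors, the signals that endothelium sends to other cells, had a median of -0.02 (0.544), with Rspo3 at 0.51 and Hbegf at -0.69. Mmp14, a membrane metalloprotease in that list, was higher by 0.35 (0.15 to 0.55) on the arrays labelled knockout without overlap, and its adjusted p over the list alone was 0.128. Medians were 0.07 for interferon response genes (0.427), with Usp18 at 0.49, Oasl2 at 0.32, Ifit2 at 0.31 and Ifit3 at 0.21, and -0.10 for p53 targets (0.0674), with Trp53inp1 at -0.57, Fas at -0.36, Perp at -0.35 and Mdm2 at -0.26. The array labelled knockout 4 was lowest among those labelled knockout for Fas (7.99) and Mdm2 (6.30). Junction and actin adhesion genes had a median of -0.03 (0.266), with Zyx at -0.35, Jam3 at -0.15, Tln1 at 0.10 and Pxn at -0.08, and basement membrane genes 0.03 (0.729), with Nid2 at 0.17, Agrn at -0.16, Col4a2 at 0.10 and Col4a5 at 0.11. Of these 8 lists 0 passed in the main comparison, with 0 members adjusted over the list alone. With all arrays kept, the shear stress, NF-kB, p53 and stress lists passed with quantile normalization and with array weights. The NF-kB, p53 and stress lists also passed with the replicate number as a random effect, and p53 targets with the filter on 50% of genes. Leaving out the array labelled wild-type 3 or knockout 3 made 5 of them pass: the stress list (mean difference -0.71 and -0.64, against -0.31 with all arrays), shear stress (-0.41 and -0.36, against -0.22), NF-kB (-0.38 and -0.32, against -0.22), interferon (0.32 and 0.27, against 0.13) and p53 targets (-0.30 and -0.22, against -0.16). The junction list passed without knockout 2, at -0.08 (adjusted p = 0.0481) against -0.03. The stress list mean was -0.02 without knockout 4, -0.07 without wild-type 1, -0.15 without wild-type 2 and -0.14 without knockout 2. Without wild-type 1 shear stress fell to -0.10, NF-kB to -0.14 and p53 targets to -0.06, and without wild-type 2 NF-kB was -0.13. Klf4 ranged from -0.25 without wild-type 1 to -1.31 without wild-type 3, with -0.42 without knockout 4, Ptgs2 from -0.77 to -2.01 without the same arrays labelled wild-type, and Edn1 was -0.12 without knockout 4, -0.10 without knockout 3 and -0.46 without knockout 1. Without wild-type 1 Klf6 was -0.38 and Zyx -0.18, and without wild-type 2 Myc was -0.21, Hbegf -0.45, Ier3 0.19 and Perp -0.17. Without wild-type 1 the interferon list turned to -0.10 and Oasl2 changed sign, and without wild-type 3 the basement membrane test turned down.

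Metabolic lists and markers of other cells completed the set. Glycolysis and hypoxia genes had a median of 0.02, a mean of -0.02 and a test direction of down (adjusted p = 0.544), with Hk1 at 0.22, Ndrg1 at -0.51, P4ha2 at -0.28 and Pdk1 at -0.60, and its direction turned without the array labelled wild-type 2 or knockout 3. Without wild-type 1 Ndrg1 was -0.32 and P4ha2 -0.09, and without knockout 3 Pdk1 was -0.37. Oxidative phosphorylation genes had a median of 0.02 (0.818), with Ndufa2 at 0.17 and Sdha at 0.16, and the direction of this test and of the arterial and basement membrane tests turned with quantile normalization, as did that of oxidative phosphorylation with median centring and without the array labelled wild-type 3, knockout 3 or knockout 4. Cytosolic ribosomal protein genes had a median of -0.02 (0.0871), with Rpl5 at -0.38, Rpl30 at -0.65, Rpl11 at -0.20 and Rpl3 at 0.22, a sign that turned with the mean of a gene's probe sets. The ribosomal mean was -0.06, and the list passed without the array labelled wild-type 3 (-0.11, adjusted p = 0.0112) or knockout 3 (-0.10, 0.0092). Fibroblast and mural genes had a median of 0.13 (0.118), with the mesenchymal transcription factor gene Tcf21 at 0.47 without overlap, Fgf10 at 0.19, Col1a1 at 0.15 and Mfap4 at 0.13. This list's mean difference was 0.15, and it passed without the array labelled wild-type 2 (0.27, adjusted p = 0.00688) or knockout 4 (0.25, 0.00372). Platelet genes had lower values in all 7 tested members, with a median of -0.18 (0.0674), among them Pf4 (-0.72), Gp9 (-0.48), Treml1 (-0.22) and Gp6 (-0.18). Its mean difference of -0.27 fell to -0.10 without the array labelled knockout 4, with Gp9 at -0.11 and Treml1 at -0.05, and to -0.10 without wild-type 1, with Pf4 at -0.43, and the list passed, at -0.45, without wild-type 3 or knockout 3. Mesothelial genes had a median of -0.01 (0.427), with Upk3b at -0.94, Lrrn4 at -0.32, Wt1 at 0.29 and Msln at 0.08. The mesothelial mean turned from -0.18 to 0.10 without the array labelled wild-type 2, as Lrrn4 did, Wt1 turned to -0.09 without knockout 4 (0.48 without knockout 3), and Msln was -0.33 without wild-type 3 and turned without knockout 1 or knockout 3 and with array weights. Erythroid genes had a median of 0.03 (0.842) over only 5 of 19 members, with Klf1 at 0.15 and Slc4a1 at 0.13, since the others were dim, had a symbol not matched, or had no probe set naming them alone. The mean of this list turned from 0.03 to -0.01 with no filter on dim genes, as it did without the array labelled wild-type 3 or knockout 3, and Slc4a1 changed sign without wild-type 3. The array labelled knockout 3 stood apart from the others labelled knockout in the means of the glycolysis (6.37), mesothelial (5.64) and angiocrine (6.94) lists. For these 7 lists too, 0 passed in the main comparison and 0 members passed adjusted over the list alone. With all arrays kept, ribosomal genes passed with quantile normalization and with array weights. Platelet genes passed with the replicate number as a random effect. Fibroblast and mural genes passed with the replicate number as a fixed block, which in effect leaves out the array labelled knockout 4.

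Genes that neighbour Sash1 were examined because a targeted allele can carry flanking variants of another strain. The test selected only 45 of 16514 genes with a position, so few neighbours were to be expected among them. A count of 0 therefore does not argue against such variants. Sash1 had 106 tested neighbours within 20 Mb, and 0 of them were among the 45 genes with an unadjusted p under 0.01 (Fisher's exact test, two-sided, p = 1). By the same exact test, 0 of 61 neighbours within 10 Mb were among them (p = 1), as was 1 of 789 genes on the whole chromosome of Sash1 (p = 0.724).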

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

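All tests of explanations in this part were chosen after the results were seen. Each of 140 named genes and 28 list means was searched for 1 array far from the other arrays labelled knockout, which chance gives in about 1 of 20 groups, and 12 genes and 4 list means had one.

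The array labelled knockout 4 stood apart in epithelial and leukocyte genes, with log2 values of 10.20 for Sftpc against 11.86 to 12 on the other arrays labelled knockout, 4.06 for Epcam against 5.14 to 5.19, and 3.51 for Ptprc against 4.57 to 4.72. Its epithelial list mean differed from the mean of the other arrays labelled knockout by -1.49 and its leukocyte list mean by -0.82. Its pan-endothelial mean differed by -0.0506, within the SD of 0.07, so the low values did not extend to that list. Quantile normalization within RMA evens out the scale of whole arrays beforehand, so this mean was no test of scaling. In both list means the array lay at least 2.97 SD from the others of its label. This held with the labels of wild-type 3 and knockout 3 kept, left out or exchanged. Because the array was picked for standing apart in genes of these lists, a large distance was set beforehand. Loss of Sash1 as the whole cause therefore stays open. A test tried before this distance also decided nothing. In the epithelial mean 3 of the 4 arrays labelled knockout lay above the lowest array labelled wild-type, but 1 of 3 without the doubted arrays. An effect that varies between embryos was not tested. Less carry-over of epithelial cells and leukocytes, which the sort on CD326 and CD45 was set to remove, may account for it. The array was lowest of 7 for 23 of 38 members, between the bounds set for and against. It was picked through members of these lists, and the members move together. The 5.43 that independent genes would give is therefore no measure of chance here, and less carry-over stays open.

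The array labelled knockout 3 stood apart in 4 list means, at 8.09 for shear stress and KLF2 genes against 7.50 to 7.55, 6.37 for glycolysis and hypoxia against 6.87 to 6.94, 6.94 for angiocrine factors against 6.73 to 6.75, and 5.64 for mesothelial genes against 5.07 to 5.14. The glycolysis mean was also below those of the arrays labelled wild-type (6.70, 6.88 and 6.77), so there knockout 3 lay with neither label. The shear stress, angiocrine and mesothelial means belong to a wider pattern. In it the arrays labelled wild-type 3 and knockout 3 each lay with the other label on the first principal component and in Sash1. Sex as its cause was argued against, since both of the 2 sides of that component held male and female embryos. An exchange of these 2 labels stays open. The split that exchanges them gave a Sash1 difference of -0.57, the lowest of the 35 splits and without overlap. For the labels as given that difference was -0.37, with overlap. An exchange predicts this, but Sash1 is part of the pattern that singled out these arrays, so this decides nothing. Cell stress during tissue preparation may also account for it and stays open. The lowest immediate early list mean among the arrays labelled wild-type 1, wild-type 2 and knockout 3 exceeded the highest among the others by 0.27. Other lists divided the same arrays, such as the glucocorticoid list at 8.01 to 8.24 against 7.03 to 7.44, so this decides nothing. The component computed without the 22 immediate early genes kept the same sides, which leaving out so few genes could hardly change. Neither explanation excludes the other, the stress list shares Dusp1 with the glucocorticoid list, and differences between litters or embryos were not tested.

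The remaining values far from the other arrays labelled knockout were these. On the array labelled knockout 4, Csrp3 was at 3.93 against 3.77 to 3.79, Fas at 7.99 against 8.54 to 8.62 and Mdm2 at 6.30 against 6.64 to 6.70. On the array labelled knockout 2, Gata1 was at 2.82 against 3.18, Krtap9-5 at 3.01 against 3.62 to 3.67, Pxn at 7.50 against 7.60 to 7.61 and Slc16a11 at 3.78 against 4.46 to 4.54. Fbxo21 was at 6.30 on the array labelled knockout 3 against 6.57 to 6.62, and Sash3 at 4.57 on the array labelled knockout 1 against 4.49 to 4.50.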

How the results depend on the processing

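The fit without the arrays labelled wild-type 3 and knockout 3 was chosen after seeing the data, and the other settings before. The count of called genes was 0 under each of the 21 refits and at a threshold of 0.1, and genes at an unadjusted p under 0.05 numbered 225 to 1779 against 556 as given, with 1310 with array weights, 367 with the replicate number as a random effect, 295 without the array labelled wild-type 2, 1314 without wild-type 3 and 1779 without both doubted arrays. Sash1 differed by -0.67 to -0.20 with an adjusted p of 0.275 to 1, so it stayed below the labelled wild-type level without passing, and the neighbour test of Sash1 never passed.

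The count of called gene lists, 4 with the labels as given, changed most. It was 10 with quantile normalization, 9 with array weights, 9 with the replicate number as a random effect, 1 without variance moderation, 0 with camera at an estimated correlation, 0 with fry, and 14 without the arrays labelled wild-type 3 and knockout 3. Leaving out 1 array at a time gave from 0 (without the array labelled wild-type 1) to 14 (without wild-type 3), with 12 without knockout 3, 2 without knockout 2 and 1 without knockout 4. Over 23 settings leukocyte markers passed in 18, cell cycle and glucocorticoid genes in 15 each and BMP and TGF-beta genes in 12, each in its direction throughout, with adjusted p up to 0.873 (cell cycle 0.914), and with sex as a covariate the BMP list missed the threshold (0.0586). These counts changed with the normalization, the moderation and the list test as well as with the arrays kept or weighted, and the cause was not tested.

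Whether the replicate numbers pair the arrays stays open. Deviations of same-numbered arrays from their label means correlated across genes at -0.18, -0.20 and -0.55. For arrays with different numbers the values ran from -0.18 to 0.49. The doubted arrays share a number, and each lay with the other label. Deviations from label means can then be opposed with or without pairing, so these correlations do not decide it. As a random effect, the replicate number had an estimated correlation of -0.26 between same-numbered arrays, so that setting treated them as opposed rather than alike. With a replicate block 1 list passed (fibroblast and mural genes), 225 genes had an unadjusted p under 0.05 and Sash1 differed by -0.30. This block in effect leaves out the array labelled knockout 4, which has no partner. Scaling moved the split of unadjusted calls, 396 higher and 160 lower as given, to 274 and 257 with median centring and to 587 and 118 with quantile normalization. Over all settings 44 values of named genes turned sign without passing, and 2852 kept theirs without passing. The test direction of 13 lists outside the called ones turned in 37 values without passing, 24 of them with arrays left out.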

Other observations

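The test of gene counts over other splits was chosen after the result was seen, and that of list counts before. The neurotensin gene Nts, a lymphatic list member, spanned the widest range among the lymphatic genes named, at 7.64, 8.23 and 5.52 on the arrays labelled wild-type and 5.04, 4.83, 8.23 and 8.23 on those labelled knockout. Interferon response genes averaged 6.34, 6.85 and 7.19 on the arrays labelled wild-type and 7.00, 7.16, 6.49 and 7.03 on those labelled knockout. The lymphatic list averaged 6.84, 6.97 and 6.02 against 6.25, 6.09, 6.83 and 6.89. Lyz1 was at 4.02 on the array labelled knockout 4 and between 8.93 and 11.09 on the others.

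Both sexes were present under both labels. Xist, transcribed from the inactive X chromosome, was at 3.19 on the array labelled wild-type 1 and 2.66 on the array labelled knockout 2, and between 9.59 and 10.71 on the others. The Y-linked gene Eif2s3y was at 6.24 and 6.69 on those 2 arrays and between 1.48 and 2.29 on the others.

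The labels gave 0 genes, which all 35 splits of the arrays into 3 and 4 reach by construction, so their number says nothing about chance. Among these splits 3 gave any gene, and the highest other split gave 86. That split set the arrays labelled wild-type 1, wild-type 2 and knockout 3 against the rest, the division already seen on the first principal component, and had 2660 genes at an unadjusted p under 0.05, so its count restates a structure of the samples that the labels do not follow. For gene lists chance could not be excluded, since 22 of 35 splits gave at least the 4 of the labels, and the highest other gave 16.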
